A study of Danio rerio with 6 samples.

How the data were processed

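Total RNA of sorted tg(myl7::gfp) cells from zebrafish embryos at 24 hpf was sequenced in 6 libraries, 3 from wildtype and 3 from Gata4 morphant embryos, per the labels. Groups were taken from the label that names the experimental group. The labels give no replicate numbers, so replicates are numbered within a group in order of deposit and pair no samples. The extract protocol in the labels names the kit of each library: mRNA-Seq for wildtype replicates 1 and 2 and morphant replicate 1, TruSeq for wildtype replicate 3 and morphant replicates 2 and 3. The labels do not say whether the wildtype embryos were injected with a control oligomer.

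A single table of the series was used, and its columns were matched to samples by the library names in the labels. The authors deposited raw counts per Ensembl gene, 1 column per library, without normalization, per the file headers and the values, which are whole numbers. The count of the most abundant gene, actb2, in morphant replicate 2 is deposited in rounded form as 1030000. The submitters' processing notes name CASAVA 1.7.0, BWA, DESeq and the genome build Zv9, with no role or order. The counting tool, the annotation release and the use of strand are not given in the sources used here, so reads shared between close paralogs (such as the myosin heavy chain or calcium pump genes) or between overlapping genes may have been split or dropped, and such genes are uncertain to that degree. No coordinates are reported.

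The same table holds values that the authors computed. RPKM values deposited by the authors were proportional to the count plus 1 within each gene, so they are above 0 where the count was 0. The authors' mean signal per group (a base mean, per the file headers) and mean RPKM equalled the means of the libraries of the group they name. The columns that the file headers give as average counts, another unit deposited by the authors, held the mean of the other group in 100% of genes within a tolerance of 1%, so these were not used. The fold (ratio) column deposited by the authors is the wildtype base mean divided by the morphant base mean. The file headers name no tool for the p-values and adjusted p-values deposited by the authors. From these, only the authors' calls were used: their number, their direction and which genes they were.

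Symbols came from a table of gene names, which matched 19189 of the 27456 gene identifiers (69.9%), holding 87.5% of the counts. Where a symbol belongs to more than 1 identifier, the identifier is printed with it. The identifiers that the name table gives for gata4 and gata6 had no line in the count table, so neither has a value here.

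Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts, terms for kit and group, and the two-sided quasi-likelihood F test. This left 18033 genes and 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common dispersion was 0.220, a biological coefficient of variation of 0.470. TMM factors were 0.997, 0.898 and 0.822 for wildtype replicates 1 to 3 and 1.291, 0.918 and 1.146 for morphant replicates 1 to 3. CPM values use TMM-scaled library totals, log2 fold changes are morphant minus wildtype with a prior count of 0.125, and medians per library use log2(CPM + 1). No 2 libraries of a group agreed within sampling noise: the chi-square per gene was 54.7 to 85.1 between wildtype libraries and 109 to 421 between morphant libraries.

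The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule names gata4, gata5, gata6 and myl7. Next come the called genes with a symbol, an absolute log2 fold change of at least 1 and the same sign in both kits. Where fewer than 5 genes pass, the rule takes the 10 genes with the smallest p, called or not, and was applied to genes with a symbol. Last come up to 4 members of each gene list with the smallest p. This gave 100 genes, of which a selection is described, and 13 more genes are named that were chosen after their values were seen (HYOU1, SDF2L1, DNAJB11, CALR, XBP1, TNNT2, TNNI1 (ENSDARG00000052708), RYR2, apobb.1, apoa1a, krt5, krt4 and lyz). The 23 gene lists covered cardiomyocyte sarcomere, atrial, ventricular, transcription factor and calcium handling genes. They also covered cell cycle, oxidative phosphorylation, glycolysis, Wnt, BMP and TGF-beta, matrix, ribosomal and mitochondrially encoded genes. Markers of endoderm and liver, erythroid, endothelial, skeletal muscle, neural, epidermal, leukocyte, yolk to notochord, and epicardial to fibroblast cells checked the sort. Of the 23 lists, 1 is not reported here, though the counts of lists include it. The ribosomal list was drawn by symbol and holds 9 genes of ribosomal S6 kinases, with a median log2 fold change of -0.36. The other 70 genes had a median of -0.41. Lists were tested on voom values with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, and were adjusted over the 23 lists. Of these, 11 passed at the preset correlation, 0 with an estimated correlation (adjusted p = 0.939 for every list) and 0 with fry (smallest adjusted p = 0.499). List calls without a kit term or with a library left out used the preset correlation.

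Alternatives were DESeq2 1.42.0 with its own size factors, limma-voom, RLE size factors, no kit term, no filter on low counts, a stricter filter (at least 5 CPM in 3 libraries), the effect within each kit, each replicate left out in turn, an adjusted p under 0.1 and a test against a fold of 1.5. Scaling by library totals alone, and the fit with neither the kit term nor morphant replicate 2, were added after seeing the data. DESeq2 gave no adjusted p for 1399 genes, which were left as missing. The procedure was tested on simulated counts for the 18033 genes, drawn from the library sizes and gene means of the 6 libraries at their estimated dispersion. A random kit effect per gene was added to the TruSeq libraries. Noise was drawn for each gene independently, so no library differed from its group across many genes together, as morphant replicate 2 did. The rates that follow may therefore differ for the real libraries. With 3 libraries per group, edgeR recovered 0% of genes changed 2-fold, 13.4% of those changed 4-fold and 59.1% of those changed 8-fold, and DESeq2 recovered 5.97%, 43.3% and 87.9%. Among unchanged genes edgeR called 3 and DESeq2 53. The changed genes numbered 67, 67 and 66, so false calls were a larger share of the DESeq2 calls than a threshold of 0.05 allows. DESeq2 adjusted p-values below are therefore given as an alternative and are likely too small. Library totals ran from 12574486 to 37906530 counts.

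For the closing section, the value that would exclude each explanation was written down before the result was seen for 4 tests (library size and a wrong label for morphant replicate 2, and both tests of the endoplasmic reticulum genes) and after it for the others. Tests of the leukocyte, skeletal muscle and neural pattern first averaged morphant replicates 1 and 3, and counted cell type lists above wildtype. They were replaced by tests over all 3 morphant libraries, because libraries must not be grouped by the outcome. The reading of the test of fewer leukocytes was also changed after its value was seen: the bound against that explanation was met, but it rests on 1 library and was then not taken to exclude it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.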

Results

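RNA was sequenced from cells sorted as cardiomyocytes from zebrafish embryos at 24 hours post fertilization (hpf). The embryos carried the transgene tg(myl7::gfp), in which the promoter of the cardiac myosin light chain gene myl7 drives green fluorescent protein, and the cells were collected by fluorescence-activated sorting. A total of 3 libraries came from wildtype embryos and 3 from embryos injected with a morpholino, an antisense oligomer that blocks translation or splicing, against Gata4, a zinc finger transcription factor of heart development. The libraries held 15302189, 21119399 and 19009161 counts in wildtype replicates 1, 2 and 3, and 12574486, 37906530 and 16779626 counts in morphant replicates 1, 2 and 3. Wildtype replicates 1 and 2 and morphant replicate 1 were made with an mRNA-Seq kit, and wildtype replicate 3 and morphant replicates 2 and 3 with a TruSeq kit. Replicate numbers follow the order of deposit and pair no samples. The labels describe pooled batches of embryos but do not state that the replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

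The comparison of morphant with wildtype cells asked which transcripts of the sorted cells differ after knockdown of Gata4. No value is given for gata4 or gata6, whose gene identifiers in the name table had no line in the count table, so the RNA of the targeted gene was not analysed here and the labels could not be checked on it. GATA5 (ENSDARG00000017821), a related heart transcription factor, had 27.8 ± 3.76 CPM (counts scaled to a common library total) in wildtype and 24.7 ± 5.45 CPM in morphants (SD, n = 3 each). Its log2 fold change was -0.08 (SE 0.34, edgeR adjusted p = 0.909), and 0.32 when libraries were scaled by their totals alone. MYL7 (ENSDARG00000019096), whose promoter drives the reporter used for sorting, had 712 ± 286 CPM in wildtype and 297 ± 78.2 CPM in morphants (SD, n = 3 each), a log2 fold change of -0.96 (SE 0.32) at an unadjusted edgeR p of 0.0196 and an adjusted p of 0.393. The gate selects on this promoter, so the value checks the sort and is no finding about the knockdown. MYL7 was lower in every morphant library (385, 237 and 268 CPM in replicates 1 to 3) than in every wildtype library (1004, 700 and 433 CPM). The sort was thus not shown to be alike in both groups, which limits the contractile genes below.

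Several genes of the heart's contractile apparatus and calcium cycling had lower values in the morphant libraries. MYH7 (ENSDARG00000079782), a myosin heavy chain, had 198 ± 40.7 CPM in wildtype and 47.0 ± 39.9 CPM in morphants (SD, n = 3 each), a log2 fold change of -2.54 (SE 0.70). SLC8A1 (ENSDARG00000013422), a sodium-calcium exchanger, had 96.8 ± 51.7 against 23.3 ± 12 CPM, a log2 fold change of -2.41 (SE 0.69). LMOD2 (ENSDARG00000045864), which nucleates actin in thin filaments, had 29.2 ± 10.3 against 9.30 ± 2.30 CPM and a log2 fold change of -1.62 (SE 0.44), and atp2a2a, a calcium pump of the sarcoplasmic reticulum, had 327 ± 70.8 against 130 ± 40.8 CPM and -1.42 (SE 0.39). These genes each had an adjusted p of 0.393 in edgeR. In DESeq2 the adjusted p was 0.0130 for MYH7, 0.0167 for SLC8A1, 0.0441 for LMOD2 and 0.0503 for atp2a2a. Without morphant replicate 2 the edgeR adjusted p was 0.00982, 0.0501, 0.0453 and 0.0412 in the same order. That fit drops the morphant library that lay with the wildtype libraries, and 3745 of 19034 genes passed in it. Passing there, here and below, is therefore weak evidence for any single gene.

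Other sarcomere genes had smaller differences of the same sign. Log2 fold changes were -1.45 (SE 0.42) for the troponin C gene tnnc1a, -1.37 (SE 0.42) for MYBPC3, the cardiac myosin binding protein C, and -0.97 (SE 0.31) for the myosin light chain gene cmlc1. The troponin genes TNNT2 and TNNI1 (ENSDARG00000052708), chosen after their values were seen, had -1.02 and -1.06. Of the 39 sarcomere genes measured, 21 had a negative and 18 a positive log2 fold change, with a median of -0.35 (camera with preset correlation, adjusted p = 0.0131, adjusted p = 0.939 with an estimated correlation). Of these genes 11 had an unadjusted edgeR p under 0.05, 0 passed the threshold adjusted over the list alone, and DESeq2 called 2 lower. The median was 0.16 without wildtype replicate 1, -0.01 without morphant replicate 1 and -0.05 without morphant replicate 2, and the list no longer passed in any of these fits (adjusted p = 0.0774, 0.141 and 0.599). Summed over the list, sarcomere genes took 10599, 5291 and 5089 CPM in wildtype replicates 1 to 3 and 5341, 3337 and 5638 CPM in morphant replicates 1 to 3, and the levels of leukocyte, skeletal muscle and neural markers given below differed between the same libraries. By a count chosen after the values were seen, 12 of the 39 genes were lower in every morphant library than in every wildtype library and 0 were higher, where chance gives 1.95 in each direction (10% in both together). The calcium handling and ion transport list had 10 of 30 genes below and 0 above, against 1.5 by chance in each direction. Such counts were not particular to heart genes. The ribosomal list had 20 of 79 below and 0 above (chance 3.95), and 1 below when scaled by library totals alone. Scaled by library totals alone, 8 sarcomere and 6 calcium handling genes were lower in every morphant library and 0 were higher, with list medians of 0.04 and 0.39 where all genes tested had 0.46. With TMM scaling the calcium handling median was -0.02 and its mean -0.29, and it did not pass (camera adjusted p = 0.151), with 3 genes at an unadjusted edgeR p under 0.05, 0 past the threshold adjusted over the list alone, and 1 lower in DESeq2. At the preset correlation that list passed camera without wildtype replicate 2 (median -0.22, adjusted p = 0.00574) and without morphant replicate 3 (median -0.47, adjusted p = 0.0150). With an estimated correlation over all libraries its camera adjusted p was 0.939.

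**Figure D1:**
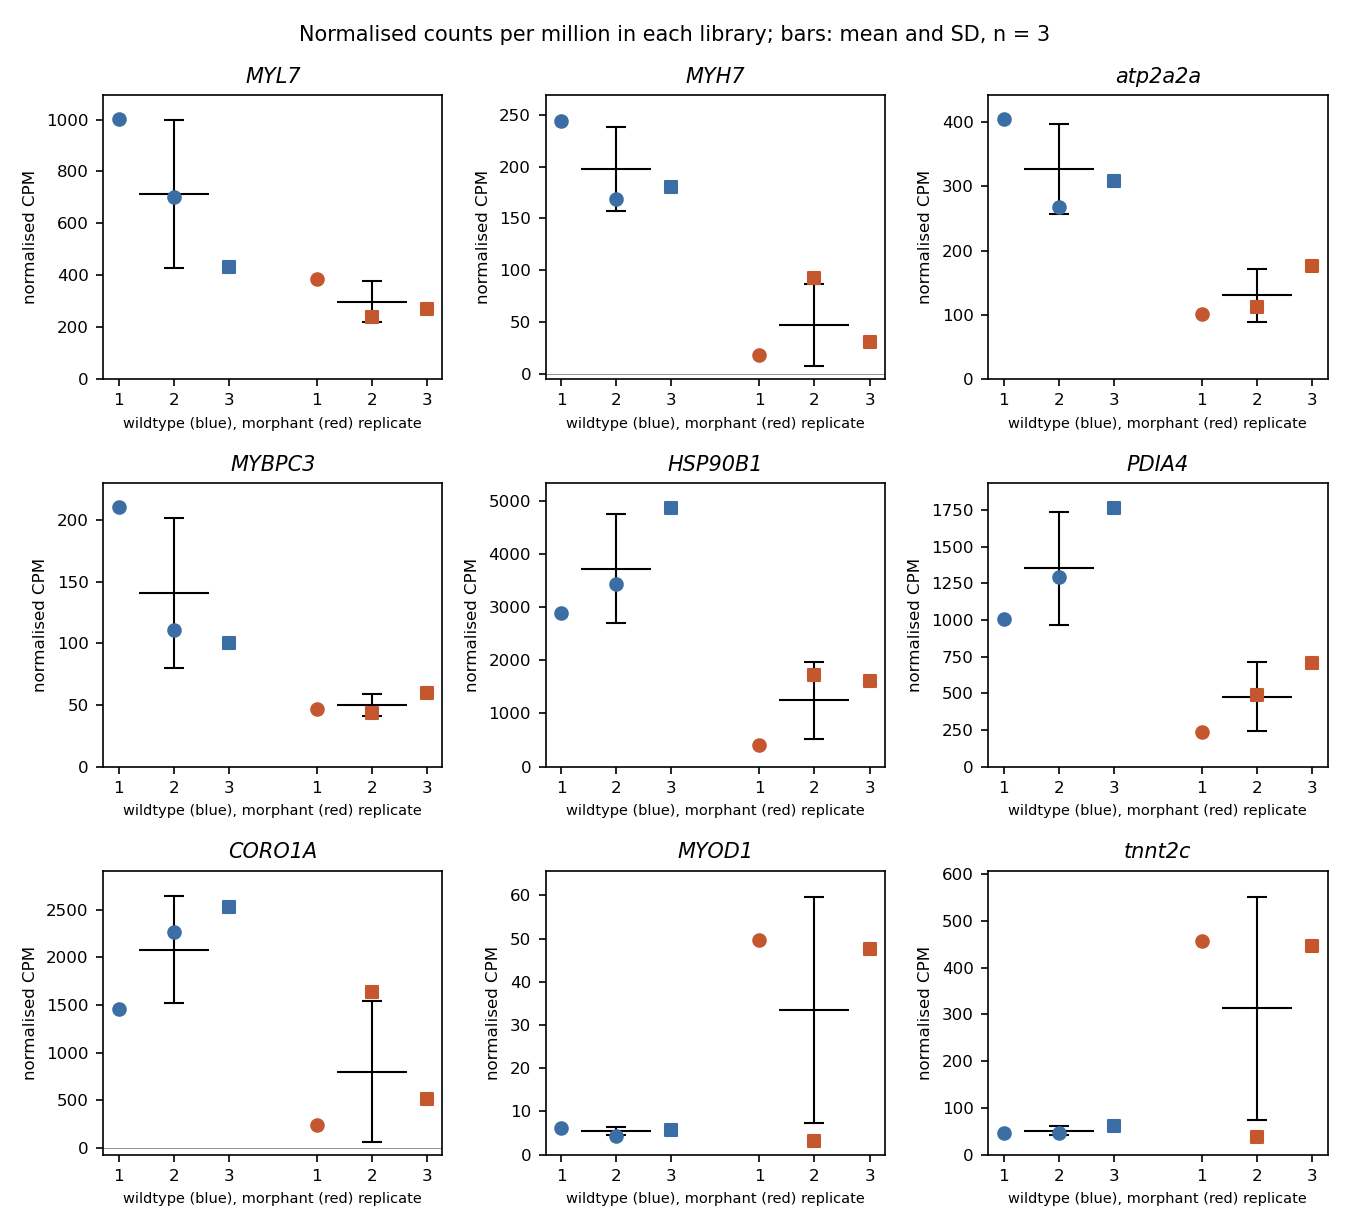
Normalised counts (CPM, TMM scaled) of 9 genes in each library, with wildtype and Gata4 morphant replicates as points and bars for the mean and SD (n = 3 each). MYH7 averaged 198 CPM in wildtype and 47.0 CPM in morphants, HSP90B1 3722 and 1243 CPM, and MYOD1 5.44 and 33.5 CPM.

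The lists of chamber genes and heart transcription factors did not pass, and their members had values on both sides of 0. Among the atrial genes, myh6, the atrial myosin heavy chain, had a log2 fold change of -1.94 (SE 0.71, edgeR adjusted p = 0.393), and nppa, the natriuretic peptide gene, had -2.36 (SE 1.35, edgeR adjusted p = 0.418). The nuclear receptor gene NR2F1 (ENSDARG00000017168) of the same list had a positive value of 2.02 (SE 0.71, edgeR adjusted p = 0.393). It had 35.0, 2.62 and 7.35 CPM in morphant replicates 1 to 3, against 3.14 to 3.75 CPM in wildtype. Within the TruSeq libraries its log2 fold change was 0.66. The atrial list had a median of -0.59 over 9 genes, 6 of them negative (camera adjusted p = 0.392), with 3 genes at an unadjusted edgeR p under 0.05, 0 past the threshold adjusted over the list alone and 0 in DESeq2. The ventricular list had a median of 0.64 over 6 genes (camera adjusted p = 0.83), and 3 genes passed the edgeR threshold adjusted over the list alone, although 0 passed over all genes tested and DESeq2 called 1, MYH7. The 3 members with the smallest p were MYH7, which was lower, and FGF8 (ENSDARG00000039615) and IRX1, which were higher with log2 fold changes of 2.86 and 2.31. TBX3, a T-box repressor, had 3.49 ± 0.985 CPM in wildtype and 15.2 ± 14.1 CPM in morphants (SD, n = 3 each), a log2 fold change of 2.30 (SE 0.63, edgeR adjusted p = 0.393, DESeq2 adjusted p = 0.0455), with 2.96 CPM in morphant replicate 2, inside the wildtype range. The homeobox gene MEIS1 had 30.4 ± 3.69 and 81.9 ± 55.8 CPM, a log2 fold change of 1.51 (SE 0.53). Morphant replicate 2 had 25.4 CPM of it, below the wildtype range of 27.1 to 34.4 CPM. The 27 heart transcription factors had a median of 0.44, 16 of them positive (camera adjusted p = 0.19, and 0.0353 without morphant replicate 2), with 8 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 1 called higher in DESeq2.

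Across all 18033 genes tested, edgeR's quasi-likelihood test with a kit term called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.393. At an unadjusted p under 0.05 there were 2261 genes, 1374 higher and 887 lower in morphants. DESeq2 called 293 genes, 123 higher and 170 lower, and limma-voom called 0, with 2250 at an unadjusted p under 0.05. Without morphant replicate 2, edgeR called 3745 of 19034 genes, 1558 higher and 2187 lower, and 284 of the 293 DESeq2 calls were among them with the same direction. Leaving out any other library gave 0 calls in edgeR. Within the mRNA-Seq libraries edgeR called 0 genes (2803 at an unadjusted p under 0.05) and within the TruSeq libraries 0 (442). TMM scaling left the median log2 fold change of all genes at 0.07, and scaling by library totals alone moved it to 0.46, with 2972 genes higher and 403 lower at an unadjusted p under 0.05 and again 0 calls in edgeR.

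Only genes with a symbol were ranked, which were 14188 of the 18033 genes tested. Among the 10 of these with the smallest edgeR p, 3 encode protein folding factors of the endoplasmic reticulum. HSP90B1 (ENSDARG00000003570), its Hsp90 chaperone, had 3722 ± 1017 CPM in wildtype and 1243 ± 726 CPM in morphants (SD, n = 3 each), a log2 fold change of -2.25 (SE 0.42, DESeq2 adjusted p = 0.00145). The disulfide isomerase genes PDIA4 (1354 ± 385 against 477 ± 236 CPM) and PDIA6 (358 ± 181 against 168 ± 77.1 CPM) had log2 fold changes of -1.93 (SE 0.36) and -1.55 (SE 0.29), with adjusted p = 0.00304 and 0.00455 in DESeq2. Also lower were shtn2 (-3.01, SE 0.54), the Ras effector gene rin1a (-2.52, SE 0.44), the receptor tyrosine kinase gene mst1ra (-2.13, SE 0.39) and si:dkey-119g10.5 (-2.39, SE 0.43). The glucose transporter gene SLC2A1 (ENSDARG00000001437) had 1.69 ± 1.02 CPM in wildtype and 25.5 ± 19.3 CPM in morphants, a log2 fold change of 4.57 (SE 0.83), and the sulfate transporter gene SLC26A1 had 4.33 (SE 0.82). The complement gene c5 had a log2 fold change of 5.14 (SE 0.78) that rested on morphant replicate 1, with 42.1 CPM there and 0.288 and 0.834 CPM in morphant replicates 2 and 3, and it was 2.96 within the TruSeq libraries. All 10 had an adjusted p of 0.393 in edgeR, and without morphant replicate 2 their adjusted p lay under 0.05 (from 0.00971 for c5 to 0.0172 for PDIA4).

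Markers of other cell types differed between the groups and within the morphant group. Leukocyte markers were lower, with a median log2 fold change of -1.90 and 26 of 27 negative. CORO1A, an actin regulator of blood leukocytes, had 2080 ± 557 CPM in wildtype and 798 ± 739 CPM in morphants (SD, n = 3 each), a log2 fold change of -2.08 (SE 0.66, edgeR adjusted p = 0.393, DESeq2 adjusted p = 0.0464). LCP1 had -2.03, the macrophage gene MPEG1 (ENSDARG00000055290) -1.90 and the metalloproteinase gene MMP9 -1.42. Summed over the list, leukocyte markers took 9475, 14960 and 18007 CPM in wildtype replicates 1 to 3, and 1617, 15984 and 4031 CPM in morphant replicates 1 to 3, so that morphant replicate 2 lay inside the wildtype range. In wildtype replicates 2 and 3 and morphant replicate 2 these sums were above those of the 39 sarcomere genes (5291, 5089 and 3337 CPM). Epidermal markers took 8294 to 18949 CPM over the 6 libraries. The gene pfn1 of that list held 3128, 4671 and 5286 CPM of this in wildtype replicates 1 to 3. In morphant replicates 1 to 3 it held 865, 4000 and 1346 CPM, so the sum depends much on that gene. The leukocyte list passed camera (adjusted p = 2.67e-11, adjusted p = 0.939 with an estimated correlation), 8 genes had an unadjusted edgeR p under 0.05, 0 passed adjusted over the list alone, DESeq2 called 1 lower, and without morphant replicate 2 edgeR called 22 of 27 lower. The median was -0.86 without morphant replicate 1 and -2.97 without wildtype replicate 3.

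Skeletal muscle and neural markers were higher. The myogenic factor genes MYOD1 (5.44 ± 0.936 against 33.5 ± 26.2 CPM) and MYOG (5.75 ± 2.53 against 34.4 ± 26.3 CPM) had log2 fold changes of 2.69 (SE 0.91) and 2.58 (SE 0.87), and the troponin T gene tnnt2c and the acetylcholine receptor gene CHRNA1 had 2.64 and 2.09. Of the 37 skeletal muscle markers 34 were positive, with a median of 1.66 (camera adjusted p = 0.000215, adjusted p = 0.939 with an estimated correlation), 17 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2. The summed level was 2813, 2117 and 2753 CPM in wildtype replicates 1 to 3 and 6888, 1519 and 8290 CPM in morphant replicates 1 to 3. Without morphant replicate 1 the median was 1.00 and the list did not pass (adjusted p = 0.316), and without morphant replicate 2 edgeR called 26 of 38 genes higher. The Notch target gene her4.1 had 0.51 ± 0.157 CPM in wildtype and 4.79 ± 3.95 CPM in morphants (SD, n = 3 each), a log2 fold change of 3.44 (SE 0.80, edgeR adjusted p = 0.393, DESeq2 adjusted p = 0.0117), and the microtubule regulator gene STMN1 (ENSDARG00000033655) and TUBA1A had 1.45 and 1.50. Of the 45 neural markers 44 were positive, with a median of 1.31 (camera adjusted p = 2.67e-11, adjusted p = 0.939 with an estimated correlation), 22 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 1 higher in DESeq2. Summed over the list, neural markers took 956, 695 and 851 CPM in wildtype replicates 1 to 3 and 2286, 1121 and 1973 CPM in morphant replicates 1 to 3. By the count chosen after the values were seen, 15 of the 45 were higher in every morphant library than in every wildtype library and 0 lower (chance 2.25 in each direction). Without morphant replicate 1 the neural median was 0.81, and without morphant replicate 2 edgeR called 22 of 46 neural genes higher.

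Endoderm and liver markers and epidermal markers were also higher, largely but not only through morphant replicate 1. FOXA2 (ENSDARG00000003411) had 12.9 and 12.3 CPM in morphant replicates 1 and 3, against 2.43 to 3.97 CPM in wildtype. The keratin gene krt97 had 37.5 and 47.0 CPM there, against 8.66 to 13.3 CPM. Morphant replicate 2 lay inside the wildtype range for both genes. The intestinal fatty acid binding protein gene FABP2 had 295 CPM in morphant replicate 1 against 0.547 and 0.782 CPM in morphant replicates 2 and 3 and 1.31 ± 1.88 CPM in wildtype (SD, n = 3), and the fibrinogen gene FGB had 42.2 CPM there against 0.777 and 1.2 CPM. Within the TruSeq libraries, which leave out that replicate, their log2 fold changes were 1.33 and 1.11, against 5.99 and 4.04 over all libraries. The 14 endoderm and liver markers were all positive, with a median of 1.53 and a mean of 2.23 (camera adjusted p = 1.6e-05, adjusted p = 0.939 with an estimated correlation), 5 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 2 higher in DESeq2. Without morphant replicate 1 their median was 0.77 and the list did not pass (adjusted p = 0.211). The apolipoprotein gene apoeb had a log2 fold change of 3.27 (SE 0.90, edgeR adjusted p = 0.393, DESeq2 adjusted p = 0.0189), and 1.78 within the TruSeq libraries. The 29 epidermal markers had a median of 1.01, 22 of them positive (camera adjusted p = 0.0137, adjusted p = 0.939 with an estimated correlation), 4 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 1 higher in DESeq2. That list did not pass without morphant replicate 1, where the median was -0.21 (adjusted p = 0.242), or without wildtype replicate 1 (median 0.24, adjusted p = 0.111).

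The remaining cell type lists did not pass. Erythroid markers had a median of -0.01 over 26 genes (camera adjusted p = 0.791), with 0 genes at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2, and passed without morphant replicate 1 (median -0.44, adjusted p = 0.00472). Endothelial and endocardial markers had a median of -0.04 over 29 genes (camera adjusted p = 0.83), with 4 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2. The endocardial factor gene NFATC1 had -1.98 (SE 0.76) and the flow-responsive factor gene klf2a -1.31 (SE 0.41), while the guidance receptor gene robo4 had 1.16 (SE 0.43). Yolk, hatching gland, lens and notochord markers had a median of -0.14 but a mean of 0.50 over 16 genes (camera adjusted p = 0.83, direction higher), with 5 at an unadjusted edgeR p under 0.05, 1 adjusted over the list alone and 2 higher in DESeq2. Epicardial, smooth muscle and fibroblast markers had a median of 0.25 but a mean of -0.10 over 21 genes (camera adjusted p = 0.83, direction lower), with 4 at an unadjusted edgeR p under 0.05 and 0 adjusted over the list alone. The 1 gene that DESeq2 called in it was MYH11, smooth muscle myosin, which had 606 ± 33.4 CPM in wildtype and 210 ± 146 CPM in morphants (SD, n = 3 each), a log2 fold change of -2.05 (SE 0.60, edgeR adjusted p = 0.393, DESeq2 adjusted p = 0.0302).

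**Figure D2:**
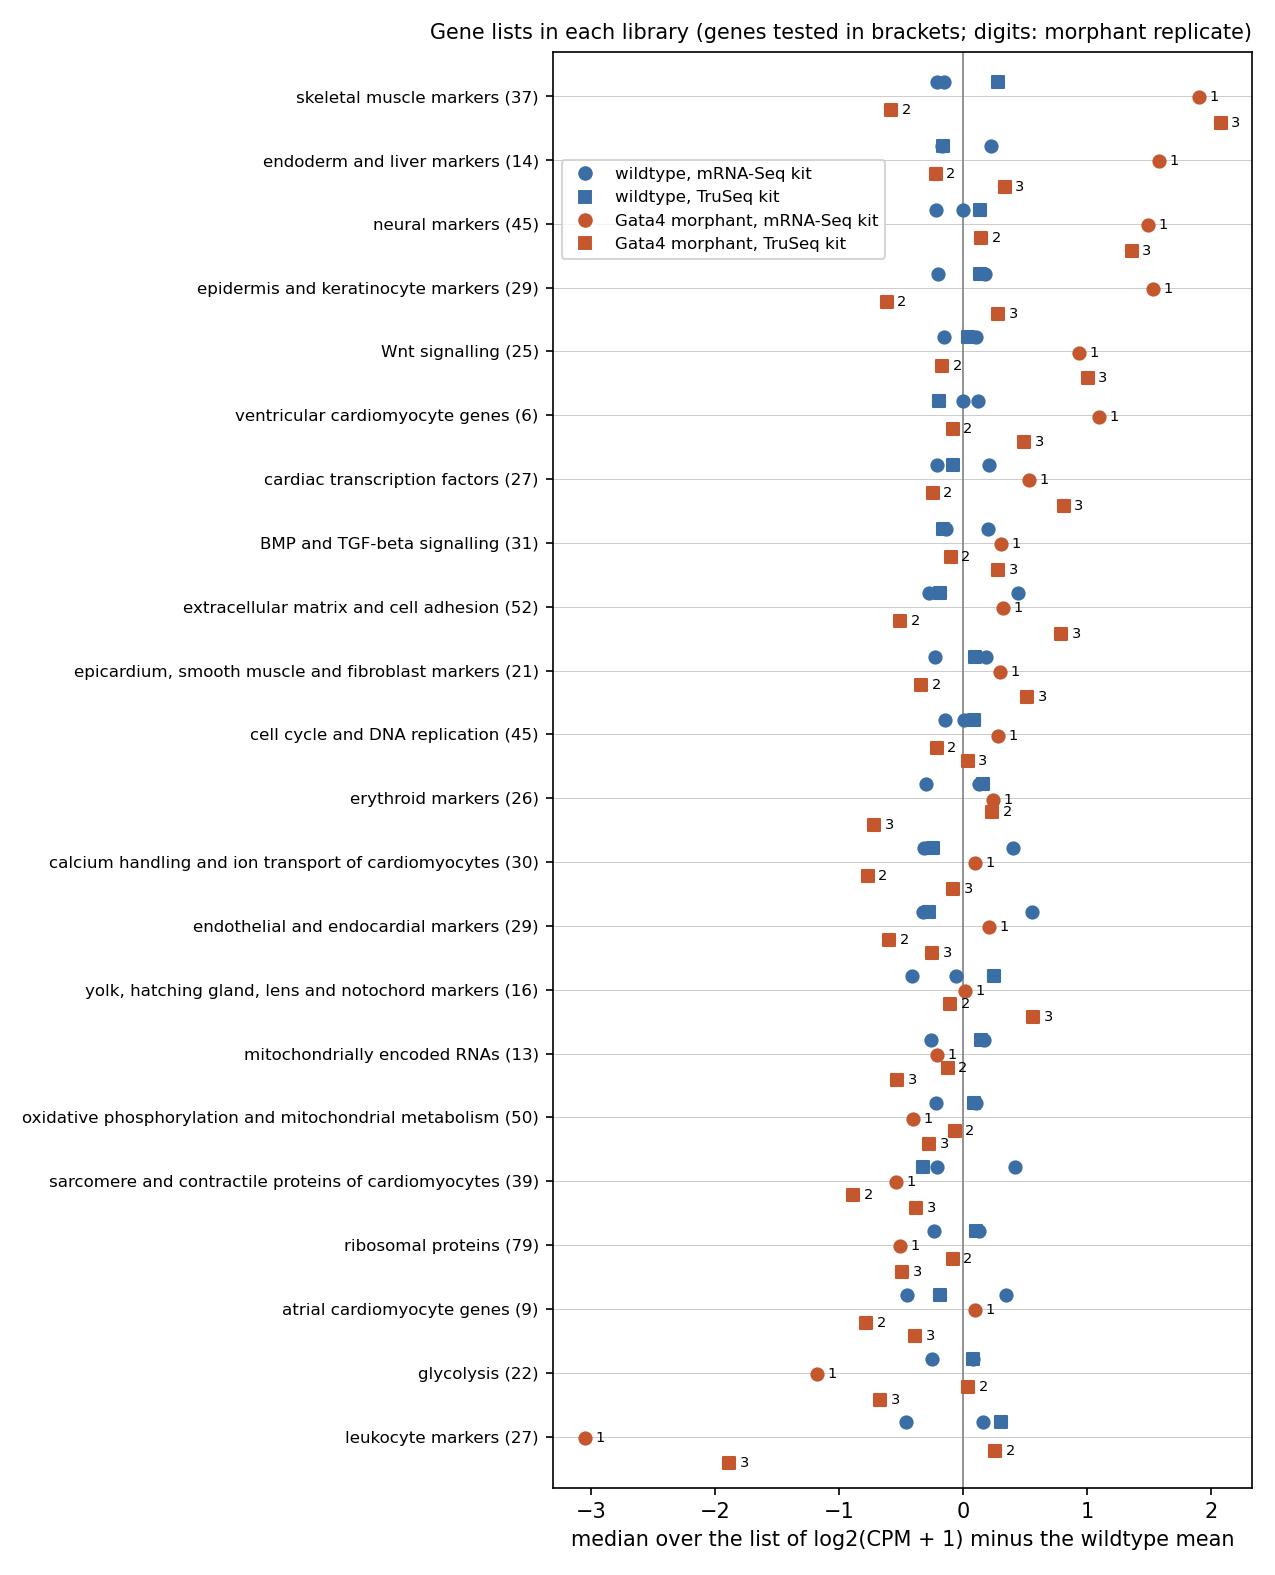
Median over the members of each gene list of log2(CPM + 1) minus the wildtype mean, with 1 point per library (colour, group; shape, kit; digit, morphant replicate). Leukocyte markers lie at -3.04, 0.26 and -1.88 in morphant replicates 1, 2 and 3, and skeletal muscle markers at 1.90, -0.58 and 2.08.

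Metabolic and ribosomal genes were lower and Wnt pathway genes higher over the morphant libraries together, but morphant replicate 2 lay within the range of the wildtype libraries or near it. Medians per library were taken as log2(CPM + 1) minus the wildtype mean. In morphant replicates 1 to 3 they were -1.18, 0.04 and -0.67 for glycolysis, with wildtype libraries at -0.25 to 0.08. For Wnt they were 0.93, -0.17 and 1.00, with wildtype libraries at -0.16 to 0.11. Leukocyte markers lay at -3.04, 0.26 and -1.88 in the same morphant libraries, and skeletal muscle markers at 1.90, -0.58 and 2.08. These lists were thus not separated from differences in cell type markers. Glycolysis genes had a median of -0.82 over 22 genes, 16 of them negative (camera adjusted p = 0.00232, adjusted p = 0.939 with an estimated correlation), with GPI at -1.71 (SE 0.72) and GAPDHS at -1.91 (SE 0.83). In that list 2 genes had an unadjusted edgeR p under 0.05. SLC2A1, which was higher, was the 1 gene called in DESeq2 and the 1 gene past the edgeR threshold adjusted over the list alone. Without morphant replicate 1 the median was -0.38 and the list did not pass (adjusted p = 0.0669). Oxidative phosphorylation genes had a median of -0.31, 46 of 50 negative (camera adjusted p = 0.000215), ribosomal protein genes -0.41, 75 of 79 negative (camera adjusted p = 4.76e-10), and the 13 mitochondrially encoded RNAs -0.27, all negative (camera adjusted p = 0.0282), each with an adjusted p = 0.939 with an estimated correlation. At an unadjusted edgeR p under 0.05 these lists held 1, 0 and 0 genes, with 0 adjusted over the list alone and 0 in DESeq2. The mitochondrially encoded list did not pass without wildtype replicate 2 (adjusted p = 0.0715), wildtype replicate 3 (0.264) or morphant replicate 3 (0.162). Scaled by library totals alone, the medians were 0.08 for oxidative phosphorylation, 0.11 for mitochondrially encoded RNAs, -0.03 for ribosomal proteins and -0.44 for glycolysis, while the median of all genes tested moved from 0.07 to 0.46. Wnt signalling genes had a median of 0.82, 23 of 25 positive (camera adjusted p = 0.00132, adjusted p = 0.939 with an estimated correlation), with 3 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2. The Wnt feedback gene NKD1 had 2.15 (SE 0.68) and the Wnt target gene SP5 2.38 (SE 0.76), and without morphant replicate 1 the Wnt median was 0.43.

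Lists of cell division, BMP and TGF-beta signalling and matrix did not pass. Cell cycle genes had a median of 0.06 over 45 genes (camera adjusted p = 0.83), with 1 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2, and a median of -0.20 without morphant replicate 1 (adjusted p = 0.0228). BMP and TGF-beta genes had a median of 0.28 over 31 genes (camera adjusted p = 0.559), with 3 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2. Extracellular matrix and adhesion genes had a median of 0.27 over 52 genes (camera adjusted p = 0.419), with 7 at an unadjusted edgeR p under 0.05, 0 adjusted over the list alone and 0 in DESeq2, and passed without morphant replicate 2 (median 0.43, adjusted p = 0.0332). In that list the collagen gene COL2A1 (ENSDARG00000069093) had 96.1 ± 14 CPM in wildtype and 481 ± 452 CPM in morphants, a log2 fold change of 2.34 (SE 0.75).

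The libraries did not separate by group alone. Across genes, which are not independent replicates, the log2 CPM of morphant replicate 2 correlated with the wildtype libraries at 0.952, 0.963 and 0.966, but with morphant replicates 1 and 3 at 0.808 and 0.887. Wildtype libraries correlated with each other at 0.942 to 0.963. On the first principal component (60.5% of the variance), wildtype replicates 1 to 3 lay at -31.8, -50.9 and -64.6, and morphant replicates 1 to 3 at 136.8, -64.6 and 75.1. In all, 2442 genes (13.5%) had all 3 morphant libraries on the same side of all 3 wildtype libraries, 1400 higher and 1042 lower, where chance gives 10%. The other splits of the libraries into 3 and 3 separated 2.84% to 30.4% of genes, and 2 of them more than the real split. Wildtype replicate 1 and morphant replicates 1 and 3 against the rest separated 5485 genes (30.4%). Wildtype replicates 1 and 2 and morphant replicate 2 against the rest separated 2791 (15.5%).

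**Figure D3:**
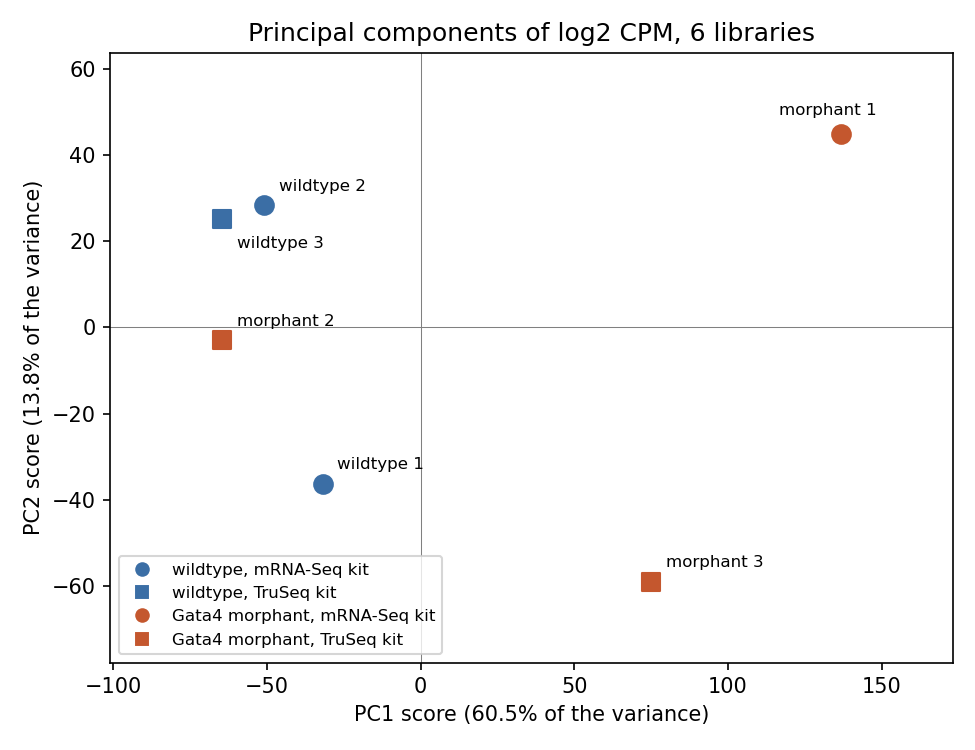
Principal components of log2 CPM over the genes tested, with 1 point per library, coloured by group and shaped by library kit. Morphant replicate 2 lies at -64.6 on the first component (60.5% of the variance), beside wildtype replicate 3 at -64.6, while morphant replicates 1 and 3 lie at 136.8 and 75.1.

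The kits were compared to size the technical difference between libraries. Several of the genes named above had values further from 0 within the mRNA-Seq libraries than within the TruSeq libraries. MYH7 had a log2 fold change of -3.55 within mRNA-Seq and -1.55 within TruSeq, SLC8A1 -3.50 and -1.34, nppa -4.46 and -0.29, and CORO1A -2.93 and -1.23. The interaction of kit and group, which tests that difference with 2 residual degrees of freedom, had 0 calls in edgeR, 824 genes at an unadjusted p under 0.05 and 115 calls in DESeq2. Between kits edgeR called 0 genes, with 950 at an unadjusted p under 0.05, and DESeq2 called 90, of which 55 were higher in TruSeq. Each kit and group combination held 1 or 2 libraries, and the TruSeq comparison included morphant replicate 2.

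The authors' deposited table listed 703 genes at an adjusted p under 0.05, of which 631 were higher and 72 lower in morphants. Of those listed higher, 258 had a value in morphant replicate 1 at least 4 times that of every other library. Among the 502 listed genes that were tested over all libraries, 106 were called in the same direction by DESeq2. The edgeR fit without morphant replicate 2 tested a different set of 19034 genes. It called 453 of the 703 listed genes in the same direction.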

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

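Scaling by library totals alone and the fit without both the kit term and morphant replicate 2 were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the labels give no replicate numbers. The alternatives for gata4 were not run, since its identifier had no line in the count table, and those for a pseudocount on normalized values were not needed for counts. edgeR called 0 genes between morphant and wildtype (2261 at an unadjusted p under 0.05). The count was 293 with DESeq2, 44 without a filter on low counts (41 higher, 3 lower), 0 to 3745 when a replicate was left out (3745 without morphant replicate 2, 0 without each of the others), and 3705 without that replicate and the kit term together. It was 0 with limma-voom, RLE size factors, no kit term, the stricter filter, library totals, either kit alone, an adjusted p under 0.10 and a test against a fold of 1.5. Between kits DESeq2 called 90 genes and for the interaction 115, against 0 each in edgeR (950 and 824 at an unadjusted p under 0.05). The log2 fold change of MYL7 stayed between -1.26 and -0.57. For the 113 named genes, 195 of 1783 values under the alternatives passed the threshold, and 11 had the other sign. Of those that passed, 86 came without morphant replicate 2 and 78 without that replicate and the kit term together. DESeq2 gave 26 and the fit without a filter on low counts 5. GATA5 was 0.017 under the stricter filter and 0.32 with library totals, where MT-CO3 was 0.039. Within the TruSeq libraries apobb.1 was -0.15, apoa1a -0.56, krt5 -1.23 and krt4 -0.13. With a replicate left out these ran from -0.20 to 7.37, -0.60 to 7.25, -1.29 to 3.79 and -0.21 to 2.69, lowest without morphant replicate 1, which held the highest value of each. Of 23 gene lists, 11 passed camera, 0 with an estimated correlation and 0 with fry, 11 without the kit term, and 9 to 12 with a replicate left out. The lists that lost their call under the estimated correlation and under fry keep their medians by construction: sarcomere -0.35, oxidative phosphorylation -0.31, glycolysis -0.82, Wnt 0.82, endoderm and liver 1.53, skeletal muscle 1.66, neural 1.31, epidermis 1.01, leukocyte -1.90, ribosomal -0.41 and mitochondrially encoded -0.27. Without the kit term calcium handling passed (median -0.11, adjusted p = 0.0108) and epidermis did not (0.94, adjusted p = 0.18). With a replicate left out, the medians of lists whose call changed ran from -0.86 to 0.16 for sarcomere, 0.049 to 0.50 for transcription factors, -0.47 to 0.15 for calcium handling, -0.20 to 0.44 for cell cycle, -1.36 to -0.38 for glycolysis, -0.085 to 0.46 for matrix, 0.77 to 2.12 for endoderm and liver, -0.44 to 0.30 for erythroid, 0.97 to 2.38 for skeletal muscle, -0.21 to 1.63 for epidermis and -0.48 to -0.21 for mitochondrially encoded RNAs. Among lists that passed in no fit, the atrial median ran from -0.86 to -0.10, the ventricular from 0.074 to 0.73, the BMP and TGF-beta from 0.085 to 0.30, the endothelial from -0.44 to 0.25, the epicardial to fibroblast from -0.098 to 0.39 and the yolk to notochord from -0.44 to 0.24. Among lists that passed in each of these fits, medians ran from -0.48 to -0.27 for oxidative phosphorylation, 0.43 to 1.03 for Wnt, 0.81 to 1.73 for neural, -2.97 to -0.86 for leukocyte and -0.58 to -0.34 for ribosomal genes. Beyond what these fits leave out by construction, the cause of the changes was not tested. In the smallest library the counting error is 28.2% at 1 CPM, and it equals the biological coefficient of variation (0.470) at 0.361 CPM, so depth limits genes near or under that level.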

Other observations

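Tests chosen after the result was seen were those of the kit and of exchanged labels for morphant replicate 2, all of those for the leukocyte, skeletal muscle and neural pattern, the splits of the libraries, the tests of the endoplasmic reticulum genes with camera and fry, and all counts of genes that separate the groups, while the bounds of the other tests were written before their values were seen.

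Several genes of protein folding and translocation in the endoplasmic reticulum had lower mean values in the morphant libraries, and 0 of them passed the edgeR threshold. Beyond HSP90B1, PDIA4 and PDIA6, the chaperone gene HYOU1 had 1825 ± 526 CPM in wildtype and 673 ± 415 CPM in morphants (SD, n = 3 each), a log2 fold change of -2.16 (SE 0.44). SDF2L1 had -1.52, the co-chaperone gene DNAJB11 -1.56, the calcium-binding chaperone gene CALR -1.54 and XBP1, a transcription factor of the unfolded protein response, -1.43 (each edgeR adjusted p = 0.393, and DESeq2 adjusted p = 0.0429, 0.0452, 0.0453 and 0.0821). Without morphant replicate 2 the edgeR adjusted p was 0.0160, 0.0140, 0.0350 and 0.0203. These genes were chosen after their values were seen.

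Some differences sat in a single library. Morphant replicate 1 held 5640 CPM of the apolipoprotein gene apobb.1, against 0.394 to 65.8 CPM in the other libraries, and 1506 CPM of apoa1a, against 0.834 to 18.2 CPM. The keratin gene krt5 had 2701 CPM there and 67.0 to 312 CPM elsewhere. The heart calcium release channel gene RYR2 had 241 CPM in wildtype replicate 1, 53.7 and 50.9 CPM in wildtype replicates 2 and 3, and 19.6 to 34.3 CPM in morphants.

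Morphant replicate 2 lay with the wildtype libraries, apart from morphant replicates 1 and 3. The kit alone did not account for this: replicate 2 correlated more with both mRNA-Seq wildtype libraries than with TruSeq morphant replicate 3 (lowest difference 0.0647, SE 0.00152). That difference comes from the same correlations that showed the pattern, so it is no separate test. A contribution of the kit was not excluded. Its larger library was argued against, since after thinning to the total of replicate 3 its mean correlation with wildtype stayed higher than with the other morphants (difference 0.112, SE 0.00196). Each SE in this paragraph takes genes as independent and measures no spread between libraries. An exchange with a wildtype library stays open. No wildtype library correlated more with the other morphants than with wildtype (highest difference -0.0797, SE 0.00171). That test takes a true morphant library to resemble morphant replicates 1 and 3. Setting wildtype replicate 1, 2 or 3 in the place of morphant replicate 2 separated 30.4%, 12.1% and 15.5% of genes, against 13.5% for the labelled groups. A wildtype library under a morphant label, or a knockdown that did not take, stays open and cannot be told apart from a weaker response with so few libraries: replicate 2 was below the 3 wildtype libraries in 41.3% of 46 folding genes not seen before (chance 25%), close to the 39.1% in which wildtype replicate 1 was lowest of the 4, and it was below them in 30 of 39 sarcomere genes (chance 9.75) but also in 26 of 37 skeletal muscle markers (chance 9.25), a list higher over the morphants.

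Leukocyte markers were lower and skeletal muscle and neural markers higher in the morphant libraries, though not in morphant replicate 2 for the leukocyte and skeletal muscle lists. A smaller share of leukocytes alone would raise all other lists alike. Skeletal muscle markers lay 2.01 (SE 0.379) above sarcomere genes in median log2 fold change, so these lists did not rise alike. They were picked after their medians were seen, however, and the SE takes genes as independent, so the test cannot exclude that explanation. For a lower purity of the sort with all other cell types entering alike, neural markers lay 1.32 (SE 0.207) above erythroid markers. They too did not rise alike, but these lists were picked in the same way, so the test cannot decide. A lower purity with cell types entering unequally was not tested. Skeletal muscle and neural cells collected with the sorted cells stay open and cannot be told apart from a change of expression within cardiomyocytes: 95.1% of the measured markers of both types had a positive log2 fold change, but these lists were picked because they were higher, and either cause would give that share. The gate on the reporter is meant to remove such cells, but markers of other cell types were present after it. Leukocyte markers summed to 14960 and 18007 CPM in wildtype replicates 2 and 3, above the sarcomere genes (5291 and 5089 CPM). The summed markers reached 8290 CPM for skeletal muscle and 2286 CPM for neural genes. In wildtype, 36 of 37 and 42 of 45 of these markers had at least 1 CPM, with 2 and 0 held by another list.

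The lower endoplasmic reticulum genes moved together, but whether they differ between the groups stays open. The 46 members not seen in the first ranking had a median log2 fold change of -0.995, and 0% of 10000 random lists of the same size and expression had a median as low (random median -0.40, 5th percentile -0.56), which takes genes as independent, while camera with their estimated correlation of 0.576 gave an unadjusted p = 0.133 and fry 0.0457. Of these 46 genes 17 were lower in every morphant library than in every wildtype library and 0 higher, where chance gives 10% in both directions together, but the split of wildtype replicate 1 and morphant replicates 1 and 3 against the rest separated 18, and their medians in morphant replicates 1, 2 and 3 were -1.30, -0.21 and -0.95. Fewer leukocytes stay open as an explanation: in replicate 2, whose leukocyte markers lay at 0.26, the difference of these genes from the leukocyte markers was -0.472 (SE 0.0842). That met the bound written beforehand against leukocytes as the cause, but it rests on a single library and, by a reading adopted after the value was seen, was not taken to exclude them.

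The splits of the 6 libraries are too few for a share under 0.05. Of the 9 splits that could be fitted with the kit term, edgeR gave 0 genes for the real split and at most 0 for any other, and a count of 0 is reached by every split, so this comparison shows nothing. DESeq2 gave 293 genes for the real split and 1101 for the highest other, and 3 of the 9 splits had as many. The splits with 1101 and 823 genes set wildtype replicate 1 or wildtype replicate 3 beside morphant replicates 1 and 3, which points to a structure of the samples. A morphant replicate 2 that differs from its label would also give such splits.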
